A study of Mus musculus with 54 samples.

How the data were processed

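RNA-seq values were deposited by the authors as log2 values for 13815 genes in 15 libraries. Per the submitters' processing notes, reads of 2 x 150 bp were demultiplexed with bcl2fastq 2.17, trimmed with Trimmomatic 0.32, aligned to mm9 with STAR 2.6.0c, and counted and normalized with SAMtools, featureCounts and limma. The maximum of the deposited log2 values was 21.47 in every library, and their quartiles ranged over libraries from 8.014 to 8.03 (lower), 9.791 to 9.799 (median) and 11.293 to 11.296 (upper), so the authors' values had been quantile normalized; the added offset is not stated. No counts were given, the depth of the RNA-seq libraries is unknown, and the genes had been filtered already, so all 13815 were tested. Deposited peak lists give the HOMER peak score of pooled ChIP libraries, per the file headers, and the score was compared within a list only. The authors' peaks were those found over input and over a background ChIP, which was a TFE3 ChIP of Tfe3 knockout liver for TFE3, and an anti-HA ChIP of liver without HA-nSREBP-1c for HA. Per the submitters' processing notes, chow TFE3 reads were processed with Trimmomatic 0.32, Bowtie2 2.2.8, SAMtools 1.7, bedtools and HOMER 4.11, and FPC reads with Trimmomatic 0.36, Bowtie2 2.2.6, SAMtools 0.1.19, bedtools and HOMER 4.4. The deposited differential list gives a log2 fold change and an adjusted p-value computed by the authors with DESeq2 in HOMER, per the file headers. Percent values were computed here from the deposited peaks and genes.

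Groups were taken from the labels: 5 RNA-seq groups of 3 libraries, and for ChIP-seq the pooled lists of TFE3 on chow (Control and LiFKO, 4 libraries each) and of TFE3 and HA on FPC diet. There was no DKO group on chow and no group lacking Tfe3 alone in RNA-seq, and the DKO mice came from a separate line, so line and genotype cannot be separated. Replicate numbers were not treated as pairs: over 30 pairs of libraries of different groups with residual correlations of -0.185 to 0.237, 7 of 15 libraries correlated best with their own number. Between chow Control and chow LiFKO, same-number pairs had 0.113, 0.17 and 0.237, and other pairs -0.188 to 0.043. Between AMLN Control and AMLN LiFKO, same-number pairs had 0.16, -0.039 and 0.231, and other pairs -0.238 to 0.11. Pairing within a diet thus stays open. The replicate block among the alternatives shared each number's effect over all groups, so it does not test this. Correlations between replicates were 0.9706 to 0.9878.

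Expression was tested with limma 3.58.1 in R 4.3.3. A test for counts had been foreseen first. As the values were log2, the branch written for that case was used: a linear model with a mean per group over all 15 libraries (10 residual degrees of freedom), contrasts, and eBayes with trend=TRUE. SE is the moderated standard error, all tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The 7 comparisons were LiFKO against Control on each diet, AMLN against chow in Control and in LiFKO, DKO against LiFKO and against Control on AMLN diet, and the difference of the LiFKO effect between diets. The 27 gene lists (lipogenesis, cholesterol synthesis, lysosome, autophagy, folliculin and Rag circuit, fatty acid oxidation, respiration, triglyceride storage, lipoprotein secretion, bile acids, glucose, endoplasmic reticulum stress, NRF2, fibrosis, macrophage, cytokine, lymphocyte, neutrophil, cholangiocyte, endothelial, hepatocyte, erythroid, acinar and adipocyte, cell cycle, interferon, acute phase and circadian genes) were tested with camera in limma at a preset correlation of 0.01, and with a correlation estimated from the data. Lists, groups, tests, named-gene rule and most alternatives were fixed before the data were examined. Of the listed markers 2 of 13 lymphocyte, 3 of 9 neutrophil and 1 of 10 acinar and adipocyte genes were measured. A symbol used by more than 1 gene occurred in 27 cases.

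Genes were named by a rule. Flcn and Tfe3 were named in every group. In each RNA-seq comparison up to 8 genes that rose and 8 that fell were eligible, with the largest absolute log2 fold change among called genes whose groups did not overlap and whose mean over 15 libraries was above the median of all genes, leaving out predicted names. Up to 4 members of each list with the smallest p were added in each comparison, and at any time Srebf1, Fasn, Acaca, Acly, Scd1, Pnpla3, Srebf2, Insig1, Gpnmb, Rragd, Fnip2, Sqstm1, Mcoln1, Ppargc1a, Ppara, Cpt1a, Fgf21, Cd36, Cidec, Pparg, Col1a1, Col3a1, Timp1, Acta2, Trem2, Cd68 and Ccl2. Peaks named were the 5 of highest score in each list and those nearest to these genes. Some genes that the rule admits are not used here. A gene named under 1 comparison could be named in another.

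Peaks were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. Peaks overlapped when they shared at least 1 bp, shares carry Wilson 95% intervals, and the background was the overlap after shifting peaks by 100 kb. Since transcription start sites were not used here, a gene had a peak when it lay within 5 kb of either end of the gene's mm9 interval. Shares of genes with a peak were compared by Fisher's exact test (two-sided) against all other tested genes, with Benjamini-Hochberg adjustment over 12 tests for changed genes and over 7 lists per peak list. To look at the effect of the shared LiFKO and Control libraries, 20 simulated sets were drawn from normal noise with each gene's residual SD. They gave too few calls to measure that effect on the calls.

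Alternatives were a replicate block, a fit of the groups compared alone, a further quantile normalization, leaving out each library in turn, an estimated correlation, a stricter threshold, other overlap rules, peaks scoring above the median of their list, equal list lengths, windows of 1 and 50 kb and a background of genes matched on expression in 20 classes. Chosen after seeing the data were a fit without the genes of lowest mean value, the replicate block for the DKO comparison, and counting peaks anywhere in the gene interval. DESeq2, other count scalings and pseudocounts were not run since the values were log2. Input libraries were not analysed here other than through the deposited lists.

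In a self-test, 200 genes were given a change in simulated values for 13815 genes. The share recovered was 29.9% at a log2 fold change of 0.5, 71.6% at 1 and 83.3% at 2, with 4 unchanged genes called and a median estimate of 2.01 at 2. The overlap and gene-end code gave 0 mismatches against brute force for 400 and 100 intervals.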

Results

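Livers of mice were studied by RNA-seq in 15 libraries and by chromatin immunoprecipitation sequencing (ChIP-seq) in 39 ChIP and input libraries. Flcn encodes folliculin, which activates RagC and RagD and so lets mTORC1 phosphorylate TFE3, a transcription factor of lysosomal genes. Mice with floxed Flcn received an adeno-associated virus carrying either GFP (Control) or Cre (LiFKO) under a hepatocyte promoter. Floxed mice that also lacked Tfe3 in the whole body and received Cre were labelled DKO. RNA-seq covered 3 libraries each of Control and LiFKO on normal chow, and of Control, LiFKO and DKO on AMLN diet, a diet rich in fat, fructose and cholesterol that induces steatohepatitis. The RNA-seq mice had 17 to 18.5 weeks of diet and a fast of 4 to 6 hours. ChIP-seq covered TFE3 on chow, and TFE3 and HA-tagged nSREBP-1c after 9 days of FPC diet (fructose, palmitate and cholesterol), with or without a virus for HA-nSREBP-1c ("1c"), the active nuclear form of the main activator of fatty acid synthesis genes. Expression was given as log2 values for 13815 genes without counts, so the depth of the RNA-seq libraries is unknown. The labels do not state that each library came from a separate mouse, and the p-values of the expression tests measure the spread between these libraries. Fisher's exact tests of peaks at genes do not measure that spread. They count genes as independent, which genes are not, and use pooled peak lists without replicates, so their p-values are descriptive.

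Flcn, the gene targeted by Cre (ENSMUSG00000032633, mm9 chromosome 11, 59604910 to 59623518), was lower in all LiFKO libraries than in all Control libraries of the same diet. Its log2 value was 11.44 ± 0.11 (SD, n = 3) in chow Control and 10.41 ± 0.23 (n = 3) in chow LiFKO. On AMLN diet it was 10.98 ± 0.07 (n = 3) in Control, 10.42 ± 0.16 (n = 3) in LiFKO and 9.49 ± 0.40 (n = 3) in the libraries labelled DKO. It fell by 1.03 in chow LiFKO (SE 0.17, adjusted p = 0.000394) and by 0.57 in AMLN LiFKO (SE 0.17, adjusted p = 0.0257). The AMLN call was lost without AMLN Control replicate 1 or 3 or AMLN LiFKO replicate 1 or 3, where the fold change stayed between -0.64 and -0.49. Tfe3 (ENSMUSG00000000134, chromosome X, 7339686 to 7352328) was not clearly lower in the libraries labelled DKO. It was 9.99 ± 0.18 (n = 3) there, against 10.24 ± 0.05 (n = 3) in AMLN Control and a range of 9.92 to 10.07 (n = 3) in AMLN LiFKO. A value for the whole gene does not show which exons were read, so it does not check the deletion, and these libraries are called "libraries labelled DKO", with DKO in the names of replicates and comparisons standing for the label only.

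**Figure D1:**
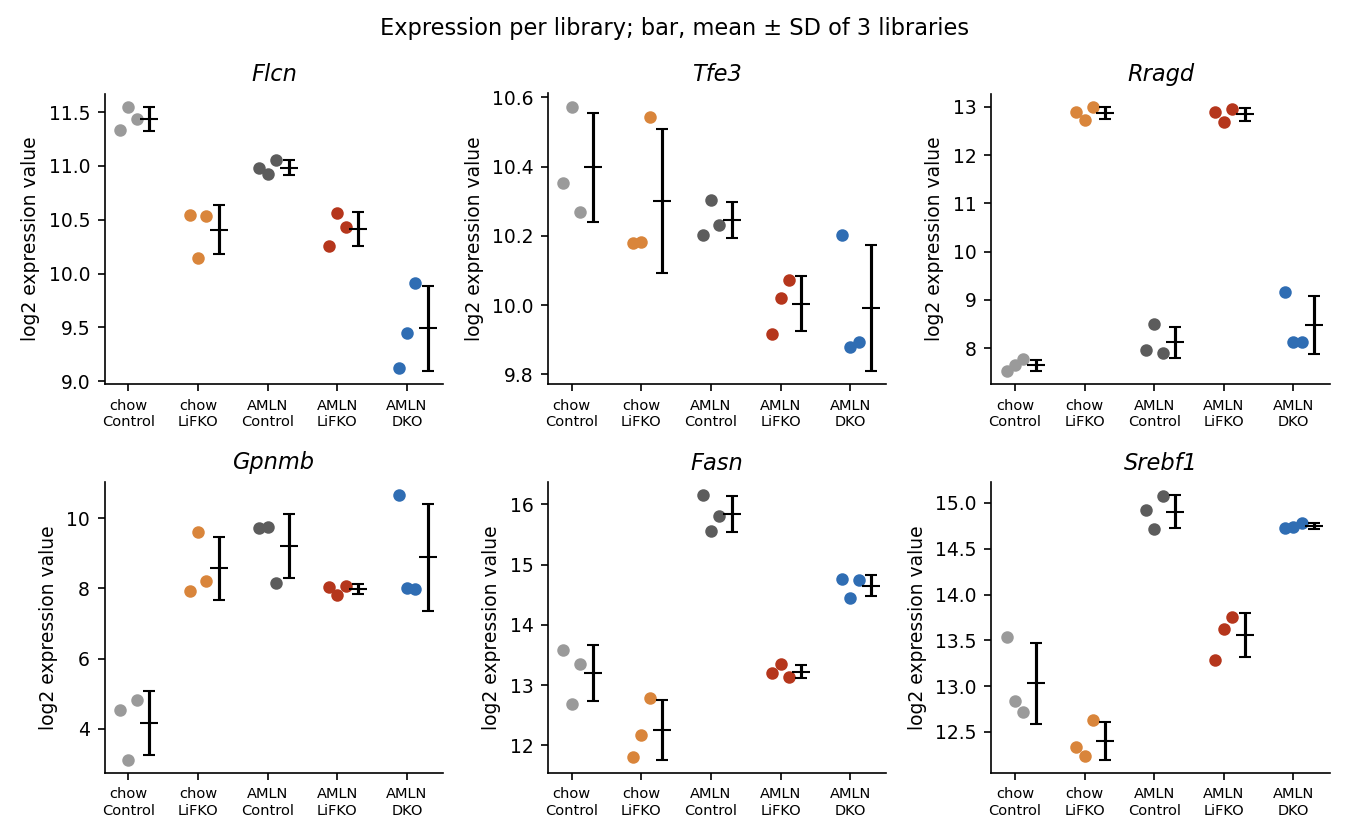
Log2 expression (y axis) of Flcn, Tfe3, Rragd, Gpnmb, Fasn and Srebf1 in each of the 15 RNA-seq libraries by group (x axis), with the mean and SD of 3 libraries per group. Rragd lay between 12.69 and 12.99 in the LiFKO libraries of both diets and between 7.53 and 9.16 in all other libraries.

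Loss of Flcn on chow asked what folliculin controls in the unchallenged liver. The largest rise among well expressed genes was in Mmp27, a matrix metalloproteinase (chromosome 9, 7571396 to 7581885), at 8.35 (log2 fold change, SE 0.19, n = 3 against 3, adjusted p = 1.07e-12). Rragd, the Rag GTPase that recruits mTORC1 to lysosomes (chromosome 4, 33070012 to 33109155), rose by 5.23 (SE 0.23, adjusted p = 4.39e-09). Gpx3, a secreted glutathione peroxidase, rose by 6.03 (SE 0.47), Apoa4, an apolipoprotein, by 5.67 (SE 0.52), and Cd63, a tetraspanin of late endosomes and lysosomes, by 5.26 (SE 0.31). Cyp46a1, a cholesterol hydroxylase, rose by 5.59 (SE 0.54), Uap1l1 by 4.78 (SE 0.37) and Cd63-ps, annotated as a Cd63 pseudogene, by 5.02 (SE 0.35). Elovl3, a fatty acid elongase, fell by 3.43 (SE 0.57), Idi1, an isomerase of sterol synthesis, by 2.96 (SE 0.54), Acot3, a peroxisomal thioesterase, by 3.13 (SE 0.77) and Akr1c19, an aldo-keto reductase, by 2.69 (SE 0.26). Slco1a1, an organic anion transporter, fell by 3.47 (SE 0.91, adjusted p = 0.0115), a call lost without chow LiFKO replicate 2. The urinary protein genes Mup7, Mup12 and Mup15 fell by 3.10, 2.69 and 2.47, and their calls held in 2, 1 and 1 of the 6 fits that left out a library, with fold changes from -3.83 to -2.12.

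Of 34 measured lysosomal genes on chow, 29 rose in LiFKO and 1 fell (29 and 1 adjusted over the list alone), with a median of 0.72 (camera adjusted p = 3.84e-22, and adjusted p = 0.00481 with an estimated correlation). They included the hydrolases Ctsa (1.49, SE 0.09), Tpp1 (1.25, SE 0.09) and Neu1 (1.31, SE 0.10) and the calcium channel Mcoln1 (1.16, SE 0.09). Of 13 genes of the folliculin and Rag circuit, 6 rose and 1 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.0164, and adjusted p = 0.148 with an estimated correlation). Besides Rragd those that rose included Gpnmb, a TFE3 target (4.41, SE 0.68), the folliculin partner Fnip2 (1.23, SE 0.18) and Rragc (0.74, SE 0.10). Of 19 autophagy genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone), among the former Atg7 (0.91, SE 0.10) and Gabarapl1 (0.76, SE 0.12). The autophagy list had camera adjusted p = 0.0276, and adjusted p = 0.328 with an estimated correlation.

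Genes of oxidative metabolism rose with them. Of 20 genes of respiration and the citric acid cycle, 19 rose and 0 fell at the limma threshold (19 and 1 adjusted over the list alone), with a median of 0.59. The list had camera adjusted p = 3.93e-14, and adjusted p = 0.125 with an estimated correlation; Ndufs1 (0.85, SE 0.08) was among its members. Of 24 genes of fatty acid oxidation, 12 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 2.63e-05, and adjusted p = 0.677 with an estimated correlation). They included Ppargc1a, a coactivator of mitochondrial genes (2.23, SE 0.23), the fatty acid transporter Cd36 (2.88, SE 0.27) and Cpt1a (0.78, SE 0.15). Of 21 genes of triglyceride storage, 6 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00873, and adjusted p = 0.677 with an estimated correlation), with Plin4 at 3.73 (SE 0.46) and Cidec at 3.28 (SE 0.67).

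Cholesterol synthesis genes were lower in chow LiFKO. Of 22 measured, 11 fell and 0 rose at the limma threshold (the same counts adjusted over the list alone), with a median of -0.67 (camera adjusted p = 1.21e-05, and adjusted p = 0.677 with an estimated correlation). Cyp51, a demethylase of the pathway, fell by 2.34 (SE 0.36) and Stard4, a sterol carrier, by 1.81 (SE 0.19). Genes of de novo lipogenesis went both ways on chow. Of 19, 4 rose and 5 fell (the same counts adjusted over the list alone), the median was -0.10, the mean 0.15 and the camera direction up (adjusted p = 0.792, and adjusted p = 0.877 with an estimated correlation). Acacb, which makes the malonyl-CoA that restrains fatty acid oxidation, rose by 4.01 (SE 0.17), Pklr, the liver pyruvate kinase, by 1.66 (SE 0.31) and Fads2, a desaturase, by 1.27 (SE 0.16). Fasn, fatty acid synthase, fell by 0.95 (SE 0.24, adjusted p = 0.0102) and Srebf1, which encodes SREBP-1c, by 0.63 (SE 0.18, adjusted p = 0.0211). Both calls were lost without chow Control replicate 1 or chow LiFKO replicate 1, and that of Srebf1 also without chow LiFKO replicate 2. Over these fits Fasn ranged from -1.21 to -0.73 and Srebf1 from -0.79 to -0.37, the last without chow Control replicate 1.

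Of 6 measured erythroid markers, 3 fell in chow LiFKO and 0 rose at the limma threshold (3 and 0 adjusted over the list alone), with a median of -1.20 (camera adjusted p = 0.0272, and adjusted p = 0.677 with an estimated correlation). Alas2 fell by 1.13 (SE 0.15), and Hbb-b2 fell by 1.49 (SE 0.39), a call lost without chow Control replicate 2 or 3 or chow LiFKO replicate 2 (range -1.90 to -1.27). Of 12 acute phase genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0349, and adjusted p = 0.758 with an estimated correlation), with Lcn2 at 2.79 (SE 0.59). Of 19 macrophage markers 3 rose, among them Cd68 (2.22, SE 0.27), and no call was made for the list (camera adjusted p = 0.588). The camera test gave no call on chow for bile acids and sterol export (adjusted p = 0.0549, and 0.0493 with a replicate block; 2 up and 6 down of 14), hepatocyte markers (0.487; 2 up and 4 down of 12), interferon response (0.54), the circadian clock (0.54; 0 up and 4 down of 11 by limma), fibrosis and cytokine genes (0.588 each), cholangiocyte markers (0.726), cell cycle and NRF2 genes (0.781 each), or lymphocyte, neutrophil and acinar or adipocyte markers (0.792 each, with 2, 3 and 1 measured). The same held for endothelial markers, lipoprotein secretion, glucose metabolism and endoplasmic reticulum stress (0.832 each). Median and mean differed in sign on chow for lipoprotein secretion (-0.16 and 0.39, test down), glucose metabolism (0.16 and -0.09, test up), endoplasmic reticulum stress (0.10 and -0.09, test up), NRF2 genes (-0.17 and 0.04, test down), macrophage markers (-0.09 and 0.14, test up) and endothelial markers (-0.12 and 0.11, test up). In all, 1723 genes rose and 1822 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and for 5784 genes (41.9%) the groups did not overlap, where chance gives 10%.

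AMLN feeding of Control mice gives the setting in which fatty liver develops. The stearoyl-CoA desaturases Scd1 (4.16, SE 0.30, adjusted p = 1.72e-06; chromosome 19, 44468941 to 44482199), Scd2 (3.80, SE 0.24) and Scd3 (4.36, SE 0.28) rose. The lipid droplet gene Cidec (3.81, SE 0.67), Apoa4 (5.40, SE 0.52), Lcn2, an iron-siderophore binding protein (3.93, SE 0.59), Saa2, an acute phase protein (3.53, SE 0.53), and Osbpl3 (3.49, SE 0.31) rose as well. Scd1 held the same log2 value of 20.65 in all AMLN Control libraries and all libraries labelled DKO, because the deposited values were quantile normalized and the gene had the same rank in each, so its fold changes against these groups carry no spread from them. The Mup genes Mup7, Mup12 and Mup1 fell by 3.86, 3.64 and 3.17 (SE 0.96, 0.81 and 0.73). Cyp2c54, a cytochrome, fell by 2.72 (SE 0.34) and Serpina1e, a protease inhibitor, by 3.20 (SE 0.52).

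Of 19 lipogenic genes, 17 rose and 0 fell on AMLN diet at the limma threshold (18 and 0 adjusted over the list alone), with a median of 1.43 (camera adjusted p = 1.76e-16, and adjusted p = 0.0146 with an estimated correlation). Fasn rose by 2.63 (SE 0.24), Srebf1 by 1.87 (SE 0.18), Pnpla3 by 4.21 (SE 0.70) and Acacb by 2.25 (SE 0.17). Of 21 genes of triglyceride storage, 13 rose and 1 fell (14 and 2 adjusted over the list alone; camera adjusted p = 1.31e-05, and adjusted p = 0.292 with an estimated correlation), with Cidea at 7.46 (SE 0.93) and Pparg at 1.36 (SE 0.23). Of 24 genes of fatty acid oxidation 5 rose (5 adjusted over the list alone; camera adjusted p = 0.00169, and adjusted p = 0.502 with an estimated correlation), and of 20 genes of respiration 4 rose (5 adjusted over the list alone; camera adjusted p = 0.00416, and adjusted p = 0.409 with an estimated correlation). AMLN Control replicate 3 stood apart over all genes. Its second principal component (23.6% of the variance) was -11.4, against -37 and -31.9 in the other AMLN Control libraries. Chow Control libraries were at 37.2 to 47.4, AMLN LiFKO libraries at -18.5 to -14.3, and libraries labelled DKO were spread from -30 to -2.1. It also stood apart in some genes of fatty acid use, such as Acot3, which is not in the oxidation list, at 8.667 against 11.795 and 12.179 in the other AMLN Control libraries. Of 12 genes of lipoprotein secretion 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0486, adjusted p = 0.0505 with a replicate block, and adjusted p = 0.292 with an estimated correlation).

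Fibrosis, macrophage and inflammation lists were called up with the diet in Control livers, while 6 lists of cell type markers had no call. Those 6 were endothelial (camera adjusted p = 0.843), cholangiocyte (0.181), lymphocyte (0.521), neutrophil (0.588), erythroid (0.318) and hepatocyte markers (0.187). Of 16 fibrosis and stellate cell genes, 8 rose (10 adjusted over the list alone; camera adjusted p = 5.23e-05, and adjusted p = 0.351 with an estimated correlation), with Col1a1 at 2.31 (SE 0.44) and Col3a1 at 2.01 (SE 0.40). Of 19 macrophage markers 8 rose (8 adjusted over the list alone; camera adjusted p = 0.000377, and adjusted p = 0.409 with an estimated correlation), among them Lgals3 (2.31, SE 0.38) and Itgax (2.92, SE 0.56). Of 12 interferon response genes 11 rose (11 adjusted over the list alone; camera adjusted p = 9.7e-07, and adjusted p = 0.292 with an estimated correlation), and of 13 cell cycle genes 8 rose (8 adjusted over the list alone; camera adjusted p = 0.000149, and adjusted p = 0.292 with an estimated correlation). Of 12 acute phase genes 8 rose (9 adjusted over the list alone; camera adjusted p = 5.23e-05), and of 10 cytokine and adhesion genes 3 rose (5 adjusted over the list alone; camera adjusted p = 0.00198), with Ccl2 at 2.66 (SE 0.51). Those lists had adjusted p = 0.292 and adjusted p = 0.351 with an estimated correlation. Cfd, an adipocyte complement factor and the 1 measured member of the acinar and adipocyte list, rose by 4.44 (SE 0.59; camera adjusted p = 0.0423, adjusted p = 0.0511 with a replicate block, and adjusted p = 0.292 with an estimated correlation). In all, 1546 genes rose and 1608 fell. The 3154 calls became 1975 and 1938 without chow Control replicate 1 or 2, and 1950 and 2024 without AMLN Control replicate 1 or 2.

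Loss of Flcn under AMLN feeding asked whether the diet's changes arise without folliculin. Mmp27 (8.03, SE 0.19, adjusted p = 1.85e-12), Cyp46a1 (5.98, SE 0.54), Rragd (4.73, SE 0.23), Gpx3 (4.18, SE 0.47), Cd63 (3.37, SE 0.31) and Cln6, a lysosomal disease gene (3.39, SE 0.22), rose in AMLN LiFKO against AMLN Control. Fasn (chromosome 11, 120667254 to 120685492) fell by 2.61 (SE 0.24, n = 3 against 3, adjusted p = 6.27e-06), and Elovl3 fell by 3.76 (SE 0.57). The glutathione transferases Gstm3, Gsta1 and Gstm1 fell by 4.74, 3.19 and 2.47 (SE 0.67, 0.68 and 0.35), the cytochromes Cyp2a4 and Cyp2c29 by 3.28 and 3.10 (SE 0.39 and 0.38), and the tubulin gene Tubb2a by 2.93 (SE 0.42). These calls held when any library of either group was left out.

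Of 19 lipogenic genes, 13 fell and 2 rose in AMLN LiFKO (the same counts adjusted over the list alone), with a median of -1.31 (camera adjusted p = 1.09e-06, and adjusted p = 0.085 with an estimated correlation). Srebf1 fell by 1.35 (SE 0.18), Pnpla3 by 3.62 (SE 0.70) and Acly by 1.05 (SE 0.24), Scd1 fell as well (adjusted p = 0.000973), while Acacb rose by 1.43 (SE 0.17). Of 22 cholesterol synthesis genes, 14 fell and 0 rose at the limma threshold (19 and 0 adjusted over the list alone; camera adjusted p = 2.56e-09, and adjusted p = 0.3 with an estimated correlation). They included Insig1, which retains SREBP in the endoplasmic reticulum (-1.23, SE 0.25). Triglyceride storage genes went both ways, 4 up and 7 down of 21 (the same counts adjusted over the list alone; camera adjusted p = 0.284). Cidea fell by 6.00 (SE 0.93) and G0s2, an inhibitor of lipolysis, by 2.18 (SE 0.26), while Plin3 rose by 1.15 (SE 0.13).

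The lysosomal list rose on AMLN diet as on chow, with 28 of 34 up and 1 down (29 and 1 adjusted over the list alone), a median of 0.64, camera adjusted p = 4.44e-22 and adjusted p = 0.00487 with an estimated correlation. Neu1 (1.54, SE 0.10), Mcoln1 (1.28, SE 0.09) and Tpp1 (1.20, SE 0.09) were among them. Of 20 respiration genes 17 rose (18 adjusted over the list alone; camera adjusted p = 3.4e-13, and adjusted p = 0.085 with an estimated correlation). Of 19 autophagy genes 9 rose and 1 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.00648, and adjusted p = 0.131 with an estimated correlation). The folliculin and Rag list had 7 up and 1 down of 13 (7 and 3 adjusted over the list alone; camera adjusted p = 0.00648, and adjusted p = 0.085 with an estimated correlation), with Fnip2 at 2.32 (SE 0.18). Fatty acid oxidation genes had 6 up and 3 down of 24 on AMLN diet (9 and 3 adjusted over the list alone; camera adjusted p = 0.284), with Ppargc1a at 2.18 (SE 0.23) and Ehhadh at -1.24 (SE 0.25).

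Interferon response and cell cycle genes were lower in AMLN LiFKO than in AMLN Control. Of 12 interferon response genes 8 fell (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.75e-05, and adjusted p = 0.339 with an estimated correlation), with Isg15 at -2.24 (SE 0.28) and Ifit1 at -2.08 (SE 0.25). Of 13 cell cycle genes 7 fell (7 adjusted over the list alone; camera adjusted p = 0.000174, and adjusted p = 0.3 with an estimated correlation), with Mcm5 at -1.53 (SE 0.32). Of 14 genes of the NRF2 and xenobiotic response 8 fell and 3 rose (the same counts adjusted over the list alone; camera adjusted p = 0.0134, and adjusted p = 0.316 with an estimated correlation), with the heme oxygenase gene Hmox1 up by 1.26 (SE 0.21). Of 12 acute phase genes 4 fell (7 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0306, and adjusted p = 0.7 with an estimated correlation). Of 16 fibrosis genes only Col1a1 fell, by 1.53 (SE 0.44, adjusted p = 0.024), and 0 passed adjusted over the list alone (camera adjusted p = 0.0306, and adjusted p = 0.743 with an estimated correlation). The Col1a1 call was lost without AMLN Control replicate 1 or 2 or AMLN LiFKO replicate 1 or 3 (range -1.86 to -1.30). Of 10 cytokine and adhesion genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.284), and of 19 macrophage markers 2 rose and 1 fell (camera adjusted p = 0.52), so neither list was called. In all, 1392 genes rose and 1330 fell (limma).

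The effects of Flcn loss on the 2 diets, which share no libraries, were alike across genes. Log2 fold changes correlated across the 13815 genes with Pearson r = 0.645 and Spearman rho = 0.522, genes not being independent replicates. On both diets 927 genes rose, where 173.6 were expected from the counts, and 721 fell, where 175.4 were expected, while 22 were called in opposite directions. Of the genes up on both diets, Rragd, Mmp27, Cd63 and Ppargc1a have been given above, and Elovl3, Stard4 and Cyp51 were among those down on both.

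**Figure D2:**
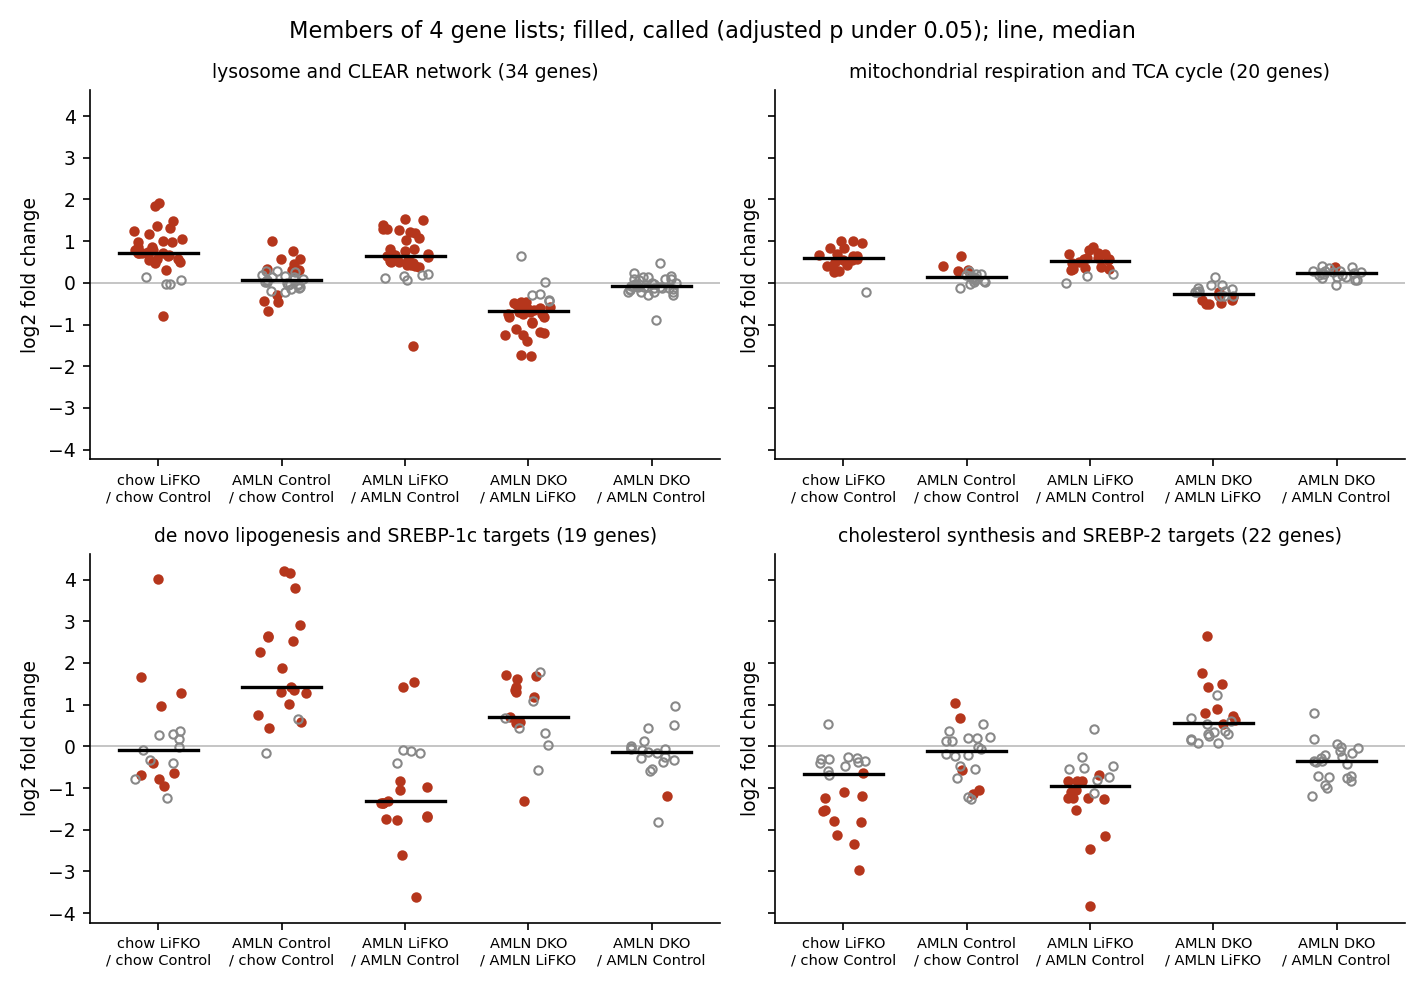
Log2 fold change (y axis) of each measured member of the lysosome, respiration, lipogenesis and cholesterol synthesis lists in 5 comparisons (x axis), filled where limma called the gene, with a line at the median. The lysosome medians were 0.72 and 0.64 for LiFKO against Control on chow and AMLN diet and -0.67 for libraries labelled DKO against LiFKO, and the lipogenesis median was 1.43 for AMLN against chow in Control.

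The difference of the Flcn effect between diets was tested directly. It was called for 144 genes, of which 105 had a lower fold change on AMLN diet and 39 a higher one. Acacb (-2.58, SE 0.25, adjusted p = 0.000196), Elovl5, a fatty acid elongase (-2.64, SE 0.37), Fads2 (-1.42, SE 0.22), Apoa4 (-5.05, SE 0.73), Osbpl3 (-3.65, SE 0.43) and Tceal8 (-3.00, SE 0.23) were lower and Npr2, a natriuretic peptide receptor (1.49, SE 0.22), was higher, with calls that held in all 12 fits that left out a library. Of 19 lipogenic genes 8 had a lower effect on AMLN diet and 0 a higher one at the limma threshold (11 and 1 adjusted over the list alone), with a median of -0.97 (camera adjusted p = 4.86e-13, and adjusted p = 0.0338 with an estimated correlation). Among these 8, Fasn (-1.67, SE 0.34, adjusted p = 0.0346) and Scd1 (-1.97, SE 0.42, adjusted p = 0.0408) kept their calls in 3 of the 12 fits each, with ranges of -1.89 to -1.40 and -2.41 to -1.75. Of 21 triglyceride storage genes 3 were lower (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.8e-07, and adjusted p = 0.288 with an estimated correlation), including Cidea (-7.45, SE 1.32), a call lost without AMLN Control replicate 1 or 2 (range -8.39 to -6.84). Gpnmb, up by 4.41 in LiFKO on chow, was at -1.23 (SE 0.68) on AMLN diet, where Control livers had already gained 5.04 (SE 0.68), and its difference was -5.64 (SE 0.97), a call lost without chow Control replicate 2 or AMLN Control replicate 1 or 2 (range -6.17 to -5.12).

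Erythroid markers were at 1.32 (median) for the difference, with 0 called by limma (2 higher adjusted over the list alone; camera adjusted p = 0.00861, and adjusted p = 0.461 with an estimated correlation). The number of differences rested on single libraries. It was 334 without AMLN Control replicate 3, but 27 without AMLN Control replicate 2, 30 without AMLN Control replicate 1 or chow Control replicate 2, 79 without chow Control replicate 1 and 86 without chow LiFKO replicate 2 or 3, and 79, 70 and 94 without AMLN LiFKO replicates 1, 2 and 3.

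Fewer genes were called for AMLN feeding in LiFKO livers, 218 up and 299 down, than in Control livers, 1546 up and 1608 down. A count of calls does not test whether the diet effect differed. The difference tested above is also that of the diet effect between LiFKO and Control, and it was called for 144 genes. Scd1 rose by 2.19 (SE 0.30, adjusted p = 0.00288), Scd2 by 2.07 (SE 0.24), Scd3 by 2.41 (SE 0.28) and Srebf1 by 1.15 (SE 0.18). The sterol exporters Abcg5 and Abcg8 rose by 1.40 and 1.24 (SE 0.13 each). Gsta2, Cyp2c29 and Cyp3a11, genes of xenobiotic metabolism, fell by 2.54, 2.32 and 2.15 (SE 0.43, 0.38 and 0.28), and Pck1, of gluconeogenesis, fell by 1.65 (SE 0.28). Of 19 lipogenic genes 6 rose (9 adjusted over the list alone; camera adjusted p = 2.77e-05, and adjusted p = 0.362 with an estimated correlation). Of 14 genes of bile acids and sterol export 4 rose (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00609, and adjusted p = 0.362 with an estimated correlation). Of 19 macrophage markers 1 passed over all genes and 9 rose adjusted over the list alone, with a median of 0.78 (camera adjusted p = 1e-05, and adjusted p = 0.478 with an estimated correlation). The 517 calls became 215 with only these groups in the fit, 188 and 175 without chow LiFKO replicate 1 or 2, and 194, 259 and 286 without AMLN LiFKO replicates 1, 2 and 3.

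The libraries labelled DKO asked which changes of LiFKO livers need Tfe3, a direction that rests on labels the Tfe3 value does not check. Flcn differed too, at 9.12 to 9.91 in the libraries labelled DKO against 10.25 to 10.56 in AMLN LiFKO. The 2 groups were thus not compared at equal Flcn transcript. Against AMLN LiFKO, Rragd fell by 4.37 (SE 0.23, n = 3 against 3, adjusted p = 6.94e-08), Gpx3 by 3.92 (SE 0.47), Mmp27 by 3.7 (SE 0.19), Cd63 by 3.69 (SE 0.31), Uap1l1 by 3.60 (SE 0.37) and Cln6 by 2.26 (SE 0.22). Gstm3 rose by 3.49 (SE 0.67), G0s2 by 2.34 (SE 0.26), Cyp2c29 by 2.26 (SE 0.38), Akr1c19 by 2.27 (SE 0.26) and Gpc1, a glypican, by 2.13 (SE 0.22). Elovl3 rose by 2.50 (SE 0.57), a call lost without AMLN LiFKO replicate 3 (range 1.97 to 2.92).

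Of 34 lysosomal genes 28 fell and 0 rose in the libraries labelled DKO against AMLN LiFKO at the limma threshold (31 and 1 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 4.27e-34, and adjusted p = 0.0008 with an estimated correlation). Neu1 fell by 1.76 (SE 0.10) and Mcoln1 by 1.11 (SE 0.09). Of 19 lipogenic genes 11 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 4.45e-07, and adjusted p = 0.0762 with an estimated correlation), with Srebf1 up by 1.19 (SE 0.18), Fasn by 1.43 (SE 0.24) and Elovl6 by 1.68 (SE 0.25), and Acacb down by 1.31 (SE 0.17). Of 22 cholesterol genes 9 rose (11 adjusted over the list alone; camera adjusted p = 2.67e-06, and adjusted p = 0.509 with an estimated correlation). Of 20 respiration genes 8 fell (12 adjusted over the list alone; camera adjusted p = 1.18e-07, and adjusted p = 0.197 with an estimated correlation), and of 19 autophagy genes 8 fell and 2 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.00118, and adjusted p = 0.0762 with an estimated correlation). Of 21 storage genes 7 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0378, and adjusted p = 0.715 with an estimated correlation), with Cidea up by 5.84 (SE 0.93). The folliculin and Rag list had 6 down and 1 up of 13 (the same counts adjusted over the list alone; camera adjusted p = 0.00105, and adjusted p = 0.0568 with an estimated correlation), with Fnip2 at -1.94 (SE 0.18). Of 19 macrophage markers 2 fell (2 adjusted over the list alone; camera adjusted p = 0.009, and adjusted p = 0.715 with an estimated correlation), and of 16 fibrosis genes Tagln, a smooth muscle actin binding protein, rose by 0.96 (SE 0.21; 2 rose adjusted over the list alone; camera adjusted p = 0.0378, and adjusted p = 0.754 with an estimated correlation). DKO replicate 1 stood apart in both lists, with Cd68 at 10.142 against 9.179 and 8.893 and Trem2 at 8.609 against 6.43 and 4.833 in the other libraries labelled DKO. In the same library Col1a1 was at 10.78 against 8.97 and 9.00 and Col3a1 at 12.82 against 11.37 and 11.44. Of 14 genes of glucose metabolism Khk, which phosphorylates fructose, rose by 0.70 (1 adjusted over the list alone; camera adjusted p = 0.00792, and adjusted p = 0.197 with an estimated correlation). In all, 698 genes rose and 825 fell, and the 1523 calls became 991 without DKO replicate 2 and 999 without AMLN LiFKO replicate 3.

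Of the 1392 genes that rose in AMLN LiFKO, 694 (49.9%, Wilson 95% interval 47.2 to 52.5) fell in the libraries labelled DKO against LiFKO. Of the 1330 that fell, 551 (41.4%, 38.8 to 44.1) rose. Independent calls would give 83.1 and 67.2 such genes. Both comparisons use the same 3 LiFKO libraries, which alone makes fold changes oppose each other. In 20 simulated sets the libraries labelled DKO were drawn with the LiFKO means. There limma called 0% of the genes in the opposite direction. This was largely fixed in advance, since no gene differed between these groups, so it does not measure what sharing adds to the shares called. The sign was opposite for 60% and 61.5% of the genes in these sets, against 98.1% and 97.4% in the data. The simulated sets shared the LiFKO libraries too, so their shares include an effect of sharing on the sign. Their noise was independent between genes, unlike real libraries, so part of the excess may still come from the shared libraries. The share called in the opposite direction was 25.9% for genes that fell without DKO replicate 2, and 39.1% for genes that rose without DKO replicate 1. Among genes with an adjusted p under 0.01 and an absolute log2 fold change of at least 1 in LiFKO, it was 67.5% for genes that rose and 69.1% for genes that fell. Against AMLN Control, the median of the genes that rose was 0.65 in LiFKO and 0.19 in the libraries labelled DKO, and that of the genes that fell was -0.62 and -0.20.

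Few genes separated the libraries labelled DKO from AMLN Control, 62 up and 28 down, with 1865 at an unadjusted p under 0.05. The 90 calls became 15 with only these groups in the fit. Mmp27 stayed up by 4.33 (SE 0.19, adjusted p = 1.15e-08), Cyp46a1 by 4.68 (SE 0.54), Dsg1c, a desmoglein, by 2.78 (SE 0.34) and Slco1a4, a transporter, by 2.49 (SE 0.26). Flcn was down by 1.49 (SE 0.17, adjusted p = 0.000882). Of the 62 genes that rose, 58 had also risen in LiFKO, where 6.2 were expected, and of the 28 that fell, 24 had also fallen, where 2.7 were expected; the AMLN Control libraries are shared, and 20 simulated sets with the libraries labelled DKO drawn at the Control means called at most 1 gene per direction, too few to measure what sharing adds. Fasn fell by 1.18 (SE 0.24, adjusted p = 0.0421), a call lost without AMLN Control replicate 1 or 3 or DKO replicate 2 or 3 (range -1.33 to -1.03). No lysosomal gene passed by limma (1 up and 1 down adjusted over the list alone; camera adjusted p = 0.0642).

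Several lists differed between the libraries labelled DKO and AMLN Control at the preset correlation, and 0 did with an estimated correlation. Respiration genes had a median of 0.24, with 1 called over all genes and 14 up adjusted over the list alone (camera adjusted p = 1.11e-09, and adjusted p = 0.228 with an estimated correlation). Interferon response genes had a median of -1.03, with 2 called and 11 down adjusted over the list alone (camera adjusted p = 1.63e-10, and adjusted p = 0.228 with an estimated correlation). Of 13 cell cycle genes none passed by limma or adjusted over the list alone, with a median of -1.05 (camera adjusted p = 2.33e-06, and adjusted p = 0.228 with an estimated correlation). Cholesterol genes had a median of -0.36 with 0 called by limma (1 down adjusted over the list alone; camera adjusted p = 0.000387, and adjusted p = 0.556 with an estimated correlation), and NRF2 genes a median of -0.53 with 2 down (7 down and 1 up adjusted over the list alone; camera adjusted p = 3.72e-05, and adjusted p = 0.228 with an estimated correlation). Erythroid markers had 1 gene down, Alas2 by 0.87 (SE 0.15), lost without AMLN Control replicate 1 or DKO replicate 3 (range -0.96 to -0.72; camera adjusted p = 0.0444, and adjusted p = 0.556 with an estimated correlation). Fatty acid oxidation genes had a median of 0.27 with 1 up (1 adjusted over the list alone; camera adjusted p = 0.00144), acute phase genes a median of -0.64 with 0 called by limma or adjusted over the list alone (camera adjusted p = 0.00144), and macrophage markers a median of -0.26 with 0 called likewise (camera adjusted p = 0.0153), each with adjusted p = 0.556 with an estimated correlation. The count of 90 was 231 without DKO replicate 1, 35 and 26 without DKO replicates 2 and 3, and 24 without AMLN Control replicate 1.

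TFE3 ChIP-seq on chow asked where TFE3 binds and whether this changes with Flcn loss. The deposited lists, each from 4 pooled libraries, held 11385 peaks in Control and 26445 in LiFKO. The highest score in both was at Tsc1, an inhibitor of mTORC1, with scores of 156.3 (mm9 chromosome 2, 28496534 to 28496720) and 245.8. Further high scores in both lay within Ppp1r10 and Unk and beside Napa. Flcn itself carried peaks in every TFE3 list, with a score of 85.2 in chow LiFKO (chromosome 11, 59623355 to 59623541), whereas Rragd had a peak within 5 kb of its ends in chow LiFKO (chromosome 4, 33070352 to 33070538) but not in chow Control. Of the Control peaks, 82.3% (Wilson 95% interval 81.6 to 83.0) overlapped a LiFKO peak, against 0.922% after a shift of 100 kb, and 35.4% (34.9 to 36.0) of LiFKO peaks overlapped a Control peak. With the same number of top peaks from each list the share was 60.9%. Scores compare within a list only, so a longer list does not show that sites were bound more strongly, and no replicate values were given for a test.

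On FPC diet the TFE3 lists held 9647 peaks in Control, 27751 in LiFKO, 10827 in Control+1c and 35325 in LiFKO+1c. Per the labels, mice without 1c had 2.5e11 genome copies of the GFP or Cre virus, and mice with 1c had 1.5e11 of it and 1e11 of the 1c virus, so the Cre dose differs wherever lists with and without 1c are compared. High scores lay in Spg11, a lysosomal reformation gene, in Snx3 and M6pr, genes of endosomal sorting, and beside Rragc (chromosome 4, 123594504 to 123594678, score 92.4 in Control). Insig1, Fasn, Srebf1 and Scd1 each had a TFE3 peak within 5 kb in the LiFKO list, with Fasn at chromosome 11, 120685446 to 120685612. Each also had one in the FPC Control list and in the chow Control list, so these genes did not gain a peak only with Flcn loss. Of the Control peaks 77.1% (76.2 to 77.9) overlapped LiFKO peaks, and 26.8% (26.3 to 27.3) of LiFKO peaks overlapped Control peaks. LiFKO peaks were in the LiFKO+1c list for 81.3% (80.8 to 81.7), while 63.8% (63.3 to 64.3) of LiFKO+1c peaks were in the LiFKO list. Control and Control+1c shared 57.6% (56.6 to 58.5) of the Control peaks. Between experiments, 58.0% (57.4 to 58.6) of chow LiFKO peaks overlapped FPC LiFKO peaks. Per the file headers, the Control, LiFKO and Control+1c lists pooled a library named as input and used one named as TFE3 ChIP of the same mouse number as its control, which limits these lists.

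HA-nSREBP-1c peaks numbered 1702 in Control+1c and 1367 in LiFKO+1c. The top peak of both lay 40 and 58 bp from Srebf2, which encodes SREBP-2 (chromosome 15, 81977480 to 81977656, score 58.9 in Control+1c). Others lay in Sc4mol and Lss, enzymes of cholesterol synthesis, and beside Pank3, a coenzyme A synthesis gene. Of the LiFKO+1c peaks 50.8% (48.2 to 53.5) overlapped a Control+1c peak, and 40.8% (38.5 to 43.2) the other way. Of the HA peaks of LiFKO+1c, 80.0% (77.8 to 82.0) overlapped a TFE3 peak of LiFKO+1c, against 1.02% after the shift, and of those of Control+1c 27.7% (25.7 to 29.9) overlapped a TFE3 peak of Control+1c. The share went with the TFE3 list and not with the HA list: 76.4% of HA Control+1c peaks overlapped TFE3 peaks of LiFKO+1c, and 27.5% of HA LiFKO+1c peaks those of Control+1c. The TFE3 lists differ in length, and with the same number of top peaks from each list the shares within LiFKO+1c and within Control+1c were 8.05% and 5.93%. The header of the LiFKO+1c list named a TFE3 library of a Control+1c mouse among the pooled HA libraries. This limits every result of that list, its overlap with TFE3 peaks and its peaks at changed genes included.

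**Figure D3:**
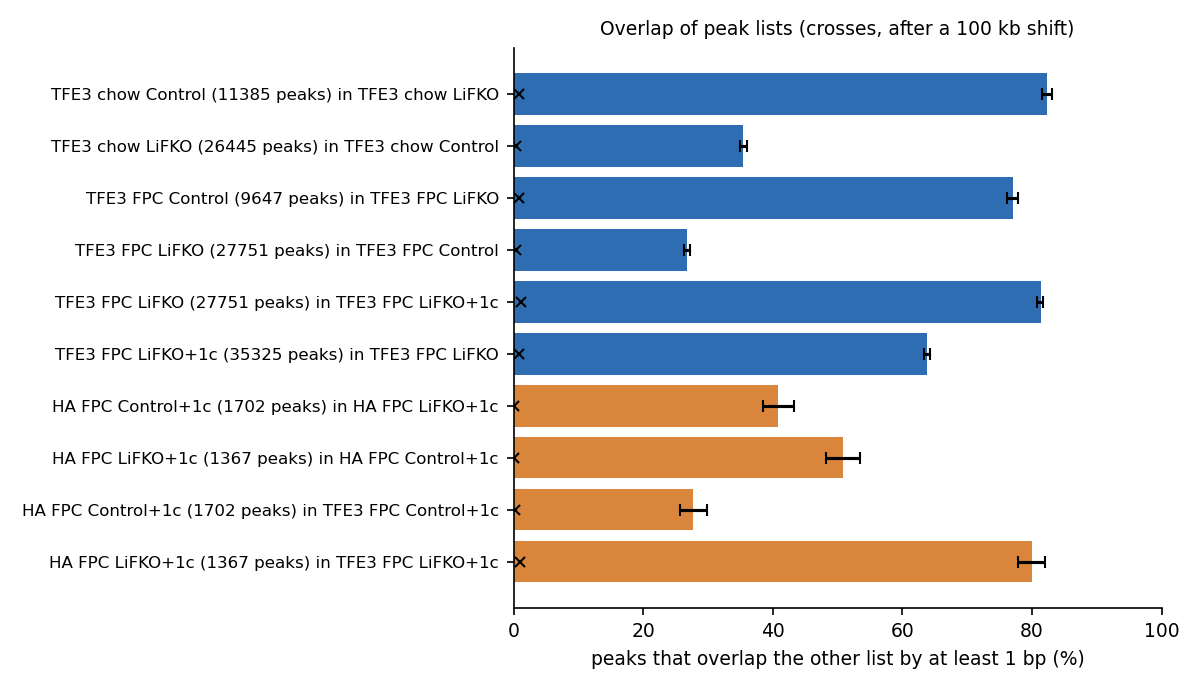
Percent of peaks of a list that overlap a peak of another by at least 1 bp (x axis) for 10 pairs of lists (y axis; TFE3 in blue, HA in orange), with Wilson 95% intervals as error bars and crosses for the share after shifting peaks by 100 kb. The share was 82.3% for chow Control peaks in chow LiFKO and 80.0% for HA LiFKO+1c peaks in TFE3 LiFKO+1c, and the shifted shares shown were at or below 1.09%.

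Lysosomal genes had TFE3 peaks more often than other genes, and lipogenic and cholesterol genes did so in some lists only. All 34 measured lysosomal genes had a TFE3 peak within 5 kb of either end in chow LiFKO, against 62.1% of other genes (Fisher's exact test, two-sided, adjusted p = 7.74e-07), and all 34 in FPC LiFKO, against 57.6% (adjusted p = 7.25e-08). Of 19 autophagy genes 19 had such a peak in chow LiFKO (adjusted p = 0.000576) and 17 in FPC LiFKO (adjusted p = 0.0101). Both lists were called in Control as well. Lysosomal genes had a peak in 31 of 34 cases in chow Control, against 35.0% of other genes (adjusted p = 9.48e-11). In FPC Control they had one in 30 of 34, against 26.9% (adjusted p = 8.18e-13). Of the 19 autophagy genes 16 had one in chow Control (adjusted p = 5.45e-05) and 12 in FPC Control (adjusted p = 0.00364). Of 24 genes of fatty acid oxidation 21 had one in FPC LiFKO (adjusted p = 0.0101). Lipogenic genes had one in 15 of 19 cases in chow LiFKO (adjusted p = 0.223) and in 16 of 19 in FPC LiFKO (adjusted p = 0.0344), and cholesterol genes in 19 and 16 of 22 (adjusted p = 0.059 and 0.274). In chow Control 12 of 19 lipogenic genes had one (adjusted p = 0.0346), and in FPC LiFKO+1c 18 of 19 (adjusted p = 0.0243) and 21 of 22 cholesterol genes (adjusted p = 0.016). The lipogenic calls did not hold in all settings. That of chow Control was lost at 1 kb and above the median score (adjusted p = 0.0863 and 0.596), and that of FPC LiFKO at 50 kb and above the median score (0.7 and 0.291). That of LiFKO+1c was lost at 1 kb, at 50 kb, above the median score and with peaks anywhere in the gene interval (0.065, 0.361, 0.0657 and 0.0833). The call for fatty acid oxidation genes in FPC LiFKO was lost at 1 kb, at 50 kb and above the median score (0.632, 0.226 and 0.217), and that for cholesterol genes in LiFKO+1c at 50 kb (0.361). HA-nSREBP-1c peaks were at 13 of 19 lipogenic genes in Control+1c (adjusted p = 2.78e-13) and 9 of 19 in LiFKO+1c (adjusted p = 9.97e-09), and at 17 and 16 of 22 cholesterol genes (adjusted p = 2.33e-18 and 6.22e-19). They were at 3 and 2 of 34 lysosomal genes (adjusted p = 0.479 and 0.552). With a window of 50 kb the TFE3 results for lysosomal genes (adjusted p = 0.0772 and 0.129) and autophagy genes (0.171 and 0.382) in chow and FPC LiFKO no longer passed, since most genes then had a peak.

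Genes that rose with Flcn loss more often had a TFE3 peak, while genes that fell did so weakly or not at all once expression was matched. In chow LiFKO, 75.5% of the 1723 genes that rose had a peak of the chow LiFKO list within 5 kb, against 60.3% of other genes (odds ratio 2.03, adjusted p = 2.92e-35), and 68.3% of the genes that fell, against 61.3% (odds ratio 1.36, adjusted p = 1.71e-08). In AMLN LiFKO the shares with an FPC LiFKO peak were 73.3% of the 1392 that rose against 55.9% (odds ratio 2.16, adjusted p = 2.92e-36) and 60.9% of the 1330 that fell against 57.3% (odds ratio 1.16, adjusted p = 0.0131). The last difference was not found with others of like expression as the background (odds ratio 0.998, adjusted p = 0.996). HA peaks of LiFKO+1c were at 5.56% of genes that fell in AMLN LiFKO against 3.04% (odds ratio 1.88, adjusted p = 8.67e-06) and at 5.24% of those that rose against 3.07% (odds ratio 1.75, adjusted p = 6.42e-05). The latter was not called with peaks above the median score (odds ratio 1.38, adjusted p = 0.115). Rragd, Mcoln1 and Fnip2 were among the genes that rose on both diets, and Fasn and Srebf1 fell with peaks of both factors.

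**Figure D4:**
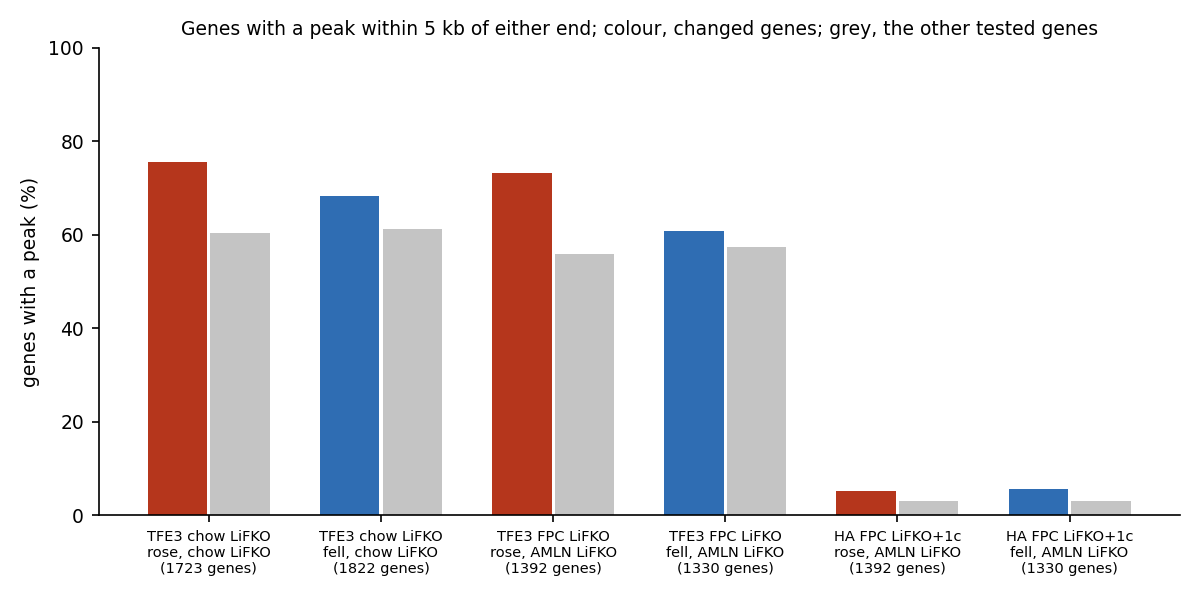
Percent of genes with a peak within 5 kb of either gene end (y axis), for genes that rose (red) or fell (blue) in LiFKO and for the other tested genes (grey), by peak list and comparison (x axis), without error bars. For chow TFE3 peaks the shares were 75.5% for genes that rose, 68.3% for genes that fell and 60.3% and 61.3% for the respective others.

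The authors' own differential list gave TFE3 peaks that were higher in LiFKO+1c than in LiFKO on FPC diet. It was made for this direction, so it says nothing about peaks that were lower. It held 96 peaks, with log2 fold changes from 1.11 to 6.97 and a median of 2.31 (DESeq2 within HOMER, per the file headers). Per its annotation 45 lay in introns, 35 between genes and 10 at promoters. Of these peaks 47 (49.0%, 39.2 to 58.8) overlapped an HA peak of LiFKO+1c, 51 an HA peak of Control+1c and 26 a TFE3 peak of the LiFKO list. The smallest adjusted p, 8.4e-09, was at an intron peak of Rims4 (chromosome 2, 163729285 to 163729449, log2 fold change 3.69), and an exon peak of Soat2, which esterifies cholesterol, had 3.63 (chromosome 15, 101988943 to 101989107). Per the file headers 1 of the 3 LiFKO libraries was named as input. Rims4 and Soat2 were picked from this list after its values were seen.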

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

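The tests of the names in the headers by the mean values of libraries and of the Control lists, all tests of the DKO labels, and the tests of hepatocyte markers and of lipogenic genes outside the top 1% were chosen only after the result was seen. The effect of Flcn loss differed between the diets, by a limma test of the difference itself, for 144 genes. Lower on AMLN diet were Cidea (-7.45), Gpnmb (-5.64), Apoa4 (-5.05), Cidec (-4.32), Lcn2 (-4.02), Osbpl3 (-3.65), Tubb2a (-3.35), Tceal8 (-3.00), Elovl5 (-2.64), Acacb (-2.58), Cd36 (-2.12), Scd1 (-1.97), Scd3 (-1.95), Scd2 (-1.73), Fasn (-1.67), G0s2 (-1.66), Apcs (-1.64), Elovl6 (-1.64), Srxn1 (-1.59), Fads2 (-1.42), Gpc1 (-1.40), Cd9 (-1.28) and Gpam (-0.97). Higher were Nr1h4 (0.67), Nr1i3 (1.1), Acnat1 (1.12), Gpcpd1 (1.16), Notum (1.22), Abca8a (1.43), Npr2 (1.49), Slco1a4 (1.95) and Hsd3b2 (2.24). Lists whose camera test of the difference passed had medians of -0.97 (lipogenesis), -0.24 (fatty acid oxidation), -0.86 (triglyceride storage), 0.41 (bile acids), -0.36 (NRF2), -0.49 (fibrosis), -0.58 (cytokines), 1.32 (erythroid), -1.74 (cell cycle), -0.92 (interferon), -1.44 (acute phase) and 0.34 (circadian). With an estimated correlation only the lipogenic list passed, and with a replicate block the NRF2 and circadian lists did not (adjusted p = 0.0538 each).

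The LiFKO effect on lipogenic genes was lower on AMLN diet than on chow, with a median difference of -0.97, although the list had no call on chow and Acacb rose on both diets. Hepatocyte markers, with a median difference of 0.215, gave no sign of a lower share of hepatocytes. This is a weak check, since the normalization sets the highest values by rank. Alb, among these markers, held the highest value, 21.47, in all Control libraries, so a lower share stays open. A single library was argued against by the highest median without any 1 library, -0.741 (without chow LiFKO replicate 3). Values capped by the authors' normalization were argued against for the 15 lipogenic genes outside the top 1% of genes in AMLN Control, whose median difference was -0.723 (at most -0.608 without 1 library, chow LiFKO replicate 3), with 4 called lower. The normalization stays open for the other 4 of the 8 called, which were in the top 1%, where it sets values by rank and Scd1 held 1 value. A cap there would lower the Control value and so hide part of a fall. A diet-dependent need for folliculin in lipogenesis is a biological explanation that was not tested apart from these, and may hold as well.

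The libraries labelled DKO did not have clearly less Tfe3 transcript, at -0.253 against AMLN Control. That they were LiFKO livers was argued against by the median of 0.188 for genes that had risen in AMLN LiFKO, and that they were Control livers by Flcn at -1.494. An allele that leaves most of the transcript cannot be told apart from other causes with a value for the whole gene. No biological explanation was tested.

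The headers of 3 FPC TFE3 lists named a library as input among pooled ChIP libraries. Had an input been pooled as ChIP with the true ChIP as its control, sites strong on chow would be missing, but the share of top chow LiFKO peaks in the FPC LiFKO list was 0.926 of that in LiFKO+1c, which argues against this for the LiFKO list. For Control and Control+1c the ratios were 0.49 and 0.447, and there it stays open, since no Control list had regular names and genotype alone could lower them. Names of input and ChIP swapped within 1 mouse stay open too. The library named input differed by -0.015 in mean log2 value over the differential peaks from the other LiFKO libraries, but these peaks had been selected as lower in LiFKO than in LiFKO+1c, and 26 of 96 overlapped a LiFKO peak, so an input could look alike there. The header of the HA LiFKO+1c list was not tested.

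Of the 10 splits of the 6 libraries in each comparison, 1, the real one, gave as many genes, and 10 splits cannot give a share under 0.05. The real count and the highest other were 3545 and 1 (chow LiFKO against Control), 3154 and 1 (diet in Control), 2722 and 3 (AMLN LiFKO against Control), 1523 and 0 (DKO against LiFKO), 90 and 20 (DKO against Control) and 517 and 1 (diet in LiFKO). For the difference between diets, 10 of 100 drawn splits gave 144 genes or more, the real one included, so chance was not excluded by this count. Of the other 9, 8 moved 4 or 6 of the libraries of a diet across genotype, the highest, 4817, exchanging the genotypes in 1 diet. Such splits carry the Flcn effect shared by both diets into the difference, which is a structure of the samples and not chance. Of 10 splits that moved 2 libraries, 1 gave as many, 247.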

How the results depend on the processing

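The replicate block for the DKO comparison, the fit without the genes of lowest mean value, and peaks anywhere in the gene interval were tested only after the results were seen. DESeq2, count scalings and pseudocounts were not run, since the values were log2, and leaving out low values by the planned rule removed no gene. Where leaving out a library left 2 in a group, they were assumed to vary like the other groups. Over 45 results that answer a comparison and 251 alternatives, 162 kept side and size, 10 lost and 3 gained a call, 74 values moved and 2 reversed. Over 68 results on genes and lists with peaks and 284 alternatives, 236 were the same, 28 lost a call, 16 gained one and 4 reversed. An estimate past the threshold in neither fit whose sign differed was counted as the same, in 2 and 30 cases. For the named genes, leaving out 1 library ended 581 and gained 74 calls in 6480 values and reversed none, with 103 changes of sign without a call. Of 946 values the replicate block ended 21 and gained 10 calls and the fit of the compared groups alone ended 64 and gained 28, while quantile normalization, which the values already had, moved none.

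With only the groups compared in the fit, DKO against Control gave 15 genes and AMLN against chow in LiFKO 215. With an estimated correlation the lists called numbered 1 for chow LiFKO, 1 for the diet in Control, 1 for AMLN LiFKO, 1 for DKO against LiFKO, 0 for DKO against Control, 0 for the diet in LiFKO and 1 for the difference between diets. Among genes with an adjusted p under 0.01 and an absolute log2 fold change of at least 1, the shares called in the opposite direction in the libraries labelled DKO were 67.5% and 69.1%. Among genes with a mean above the median Pearson r between the diets was 0.718.

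With at least 50% of both peaks shared, among peaks scoring above the median of each list, and with the same number of top peaks, the overlaps were 78.2%, 91.1% and 60.9% for chow Control in LiFKO, 73.5%, 82.3% and 43.8% for FPC Control in LiFKO, 55.4%, 65.6% and 55.7% for Control in Control+1c, 77.7%, 89.1% and 73.6% for LiFKO in LiFKO+1c, 73.3%, 75.9% and 38.2% for Control+1c in LiFKO+1c, and 72.7%, 70.9% and 8.05% for HA in TFE3 peaks of LiFKO+1c. Above the median score, HA LiFKO+1c in HA Control+1c was 69.9% and HA in TFE3 peaks of Control+1c 22.5% (5.93% with the same number).

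For genes that fell in AMLN LiFKO and FPC LiFKO peaks, the odds ratio was 1.07 at 1 kb (adjusted p = 0.282), 0.988 above the median score (0.861) and 0.998 against genes matched on expression (0.996), the last 2 on the other side of 1. Shares of list members with a TFE3 peak (Fisher's exact test) were, at 1 kb, 12.5% for fatty acid oxidation in FPC Control (adjusted p = 0.788) and 54.2% in LiFKO+1c (1), both below other genes, 50% in FPC LiFKO (0.632), and 76.9% for the folliculin and Rag list in FPC LiFKO (0.0383). At 50 kb they were 100% for lysosome and autophagy in chow LiFKO (0.0772 and 0.171) and for lysosome, autophagy and fatty acid oxidation in FPC LiFKO (100%; 0.129, 0.382 and 0.226), and 94.7% for lipogenesis (0.7). Above the median score they were 77.3% for cholesterol genes in chow LiFKO (0.0112), and 57.9% for lipogenesis (0.291) and 58.3% for fatty acid oxidation (0.217) in FPC LiFKO. Within the gene interval, lipogenesis in chow LiFKO reached 94.7% (0.0285).

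Leaving out each library in turn, counts ranged from 1938 (without chow Control replicate 2) to 3257 for the diet in Control, 991 (without DKO replicate 2) to 1280 for DKO against LiFKO, 24 (without AMLN Control replicate 1) to 231 (without DKO replicate 1) for DKO against Control, 175 (without chow LiFKO replicate 2) to 497 for the diet in LiFKO, and 27 (without AMLN Control replicate 2) to 334 (without AMLN Control replicate 3) for the difference between diets. The shares called in the opposite direction in the libraries labelled DKO ranged from 39.1% (without DKO replicate 1) to 55.6% for genes that rose and from 25.9% (without DKO replicate 2) to 48.9% for genes that fell, both highest without AMLN Control replicate 1.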

Other observations

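Of 14 bile acid and sterol export genes, a list without a camera call on chow, 6 fell and 2 rose in chow LiFKO. Among those that fell were Cyp27a1, which starts the acidic pathway (-1.01, SE 0.12), Abcb11, the bile salt export pump (-1.05, SE 0.15), and Nr1h4, the bile acid receptor (-0.58, SE 0.10). Of 11 circadian clock genes, also without a call for the list, 4 fell, among them Per3 at -0.98 (SE 0.16) and Dbp at -1.08 (SE 0.28), the latter -0.69 without chow LiFKO replicate 2. Alb, albumin, held the highest value, 21.47, in all chow Control libraries and 20.10 or 20.65 in chow LiFKO, so its fall of 1.00 (SE 0.28) is a step between ranks of quantile normalized values. Stab2 and Lyve1, scavenger receptors of sinusoidal endothelium, rose by 1.02 (SE 0.14) and 1.33 (SE 0.27) on chow, and Stab2 rose by 1.45 (SE 0.14) in AMLN LiFKO, while the other 9 endothelial markers passed in neither comparison.

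Gpnmb was at 10.66 in DKO replicate 1 and at 8.02 and 7.98 in the other 2 libraries labelled DKO. In AMLN LiFKO livers Apoe, a lipoprotein ligand that macrophages also make, rose by 1.37 (SE 0.24) against AMLN Control and fell by 1.37 (SE 0.24) in the libraries labelled DKO against LiFKO. Apoe held 1 value within each group, 21.47 in all LiFKO libraries, because its rank set its quantile normalized value, so these are steps between ranks. Of the 927 genes up in LiFKO on both diets, 577 were called down in the libraries labelled DKO against LiFKO, and 422 of these had TFE3 peaks within 5 kb in both the chow and the FPC LiFKO lists. Beyond chow LiFKO, the median and the mean or camera direction of a list also differed in sign, in lists without a call, for the folliculin and Rag list and endothelial markers (diet in Control), bile acid genes, cholangiocyte and erythroid markers (AMLN LiFKO), and lipoprotein and endoplasmic reticulum stress genes (DKO against LiFKO). The same was seen for the folliculin and Rag, bile acid, endoplasmic reticulum stress and hepatocyte lists (DKO against Control), storage, glucose, hepatocyte, cell cycle, acute phase and circadian lists (diet in LiFKO), and the folliculin and Rag and macrophage lists (difference between diets).

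The tests of sex-biased genes in this part were chosen only after the result was seen, and the other tests were planned. TFE3 sat more often at genes that rose in AMLN LiFKO and fell again in the libraries labelled DKO than at other genes that rose, 78.7% against 67.9% (odds ratio 1.74, Fisher's exact test, two-sided, p = 7.02e-06). Genes were not matched on expression here, and matching had lowered the odds ratio of all genes that rose from 2.16 to 1.73. The peaks were those of the FPC LiFKO list, whose header named an input library. Direct binding may mark part of these genes, but expression was not set apart, and their dependence on Tfe3 rests on the labels. For genes that fell and rose again the odds ratio was 1.15 (Fisher's exact test, p = 0.254), which gives no such mark. Genes whose LiFKO effect was lower on AMLN diet more often had an HA-nSREBP-1c peak of Control+1c, 11.4% against 4.56% (odds ratio 2.70, Fisher's exact test, p = 0.00322), among them Fasn, Scd1, Scd2, Acacb and Fads2. Of the 12 genes with such a peak, Fads2, Gpam, Fasn, Scd2, Scd1 and Acacb belong to the list of lipogenesis and SREBP-1c targets. That list was already called for the difference, so the result partly restates it. Genes were not matched on expression, and the number of differences rested on single libraries. Sites of nSREBP-1c may mark some of the genes with a called difference.

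The falls of Mup genes, Slco1a1 and Elovl3 raised the hypothesis that male-biased genes fell and female-biased genes rose in LiFKO. The male-biased list holds the genes that raised it, so its fall restates them and was not used as a test. Of 15 female-biased genes 0 rose and 5 fell on chow (limma; 2 and 5 adjusted over the list alone; median 0.162, camera p = 0.456), and 2 rose and 6 fell on AMLN diet (median -0.18, camera p = 0.0263, and 0.185 with an estimated correlation). Several female-biased genes thus fell, and the hypothesis was not borne out. Of 27 male-biased genes, 12 fell and 2 rose in LiFKO on chow, and 4 fell and 2 rose on AMLN diet (limma). With AMLN diet in Control livers 15 fell and 0 rose, so such a fall was not particular to LiFKO. Why these genes fell was not tested.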
